A study of Mus musculus with 16 samples.

How the data were processed

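The 16 samples were mouse kidney preparations of wild type and Gulo-/- animals on the strain named in the labels as C57BL/6. Gulo encodes the enzyme of the last step of ascorbate (vitamin C) synthesis. Each of 4 assays (single-cell RNA sequencing, whole-genome bisulfite sequencing, m6A immunoprecipitation sequencing and the RNA sequencing made with it) had 2 wild type and 2 Gulo-/- samples. Groups were taken from the genotype in the labels, which also say that the kidneys were cut up and pooled before being divided over the assays. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, and cells are not replicates.

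The deposited matrices of the 4 single-cell libraries hold raw UMI counts per gene and barcode. They were used without change, and the tool that counted them is not given in the sources used here. The authors' processing notes name genome build mm10, Seurat 2.3.4 and MACS2 2.1.2. For bisulfite sequencing, the authors' deposited table of differentially methylated regions gives other values: the mean methylation level (0 to 1) on each side of the comparison, their difference, the number of CpGs, the distance to the transcription start and an annotation. It also gives an area statistic, a score made by the authors and taken as deposited, whose calculation is not given in the sources used here and which no result uses. The table holds no values per sample, no coverage and no genotype for side 1 or side 2, so its values carry no replicate error and its direction is given by side. A deposited table of marker genes of the authors' cell clusters gives a p-value with cells as units and a natural log (ln) ratio. The m6A and bulk RNA sequencing samples were not analysed here.

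Barcodes with at least 500 UMIs, at least 200 genes and at most 50% of UMIs from mitochondrial genes were kept. Sex was read from Xist and Ddx3y counts, since the labels give none: wild type replicate 1 and Gulo-/- replicate 2 were female, and wild type replicate 2 and Gulo-/- replicate 1 were male. Of the barcodes of wild type replicate 2, 986 were also in wild type replicate 1, where 33.5 were expected by chance, and these were removed from replicate 2. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 0 doublets in wild type replicate 2, so the highest scores were removed up to the share expected for the number of cells, which took 20, 559, 28 and 1559 barcodes. The libraries were clustered together with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1 and seed 0. The 38 clusters were named from fixed marker lists, and clusters 20, 23, 31, 33 and 36 stayed unnamed. Among its leading genes cluster 20 held 4 intercalated cell markers and 1 principal cell marker, and cluster 31 held 3 endothelial markers. Cluster 23 scored highest for the endothelial list. The cells of these clusters are not counted in the intercalated cell-like and endothelial-like shares. Names carry "-like", since they rest on marker genes. Clustering each library alone gave 92.45% of the cells the same class.

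UMI counts were summed per library and class and compared between genotypes with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, robust), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The plan was to test classes with at least 50 cells in every library, which the proximal tubule-like and endothelial-like classes met. A minimum of 20 cells added thick ascending limb-like, distal convoluted and connecting tubule-like, and macrophage and monocyte-like cells. A class-by-genotype interaction was tested with the library as a term. Gene lists (28) and marker lists of cell types (20) were tested with camera in limma 3.58.1 on log CPM (UMI counts scaled to a common total) with a prior count of 2, a preset correlation of 0.01 and adjustment over the lists of a class, and repeated with an estimated correlation and with fry. Shares of cells were compared by a two-sided exact permutation test over 6 splits, whose smallest p is 0.333. Directions of methylation differences were compared between annotation classes by two-sided Fisher's exact tests, with regions as units that are not independent. Genes with a promoter region of either direction were tested as sets by camera.

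The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. That rule took, among called genes whose libraries of one genotype all lay beyond those of the other, up to 12 per direction in proximal tubule-like cells and 4 in other classes, with called list members besides. Up to 4 list members that were not called could be given as values, and gene models without a name were only counted. Of the authors' regions, the 8 promoter regions with the largest differences per direction were named. Chosen after seeing the data were the removal of shared barcodes, the share of doublets removed, the minimum of 20 cells, the sex block, cluster 23 counted as endothelial-like, the fits of S1-like cells under other models, the fits of the promoter sets with blocks, with libraries left out and in S1-like cells, the comparison of regions near marker genes, the comparison of clusters within the proximal tubule-like class, and all values on or without chromosome 14.

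Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, only genes at least as high in a class as in all cells, a mitochondrial limit of 25%, no doublet removal, separate clustering, equal cell numbers, the replicate number as a block and each library left out. When a group is left with 1 library, edgeR assumes that it varies like the other group. The replicate number was not the main term because the labels do not say what it marks.

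The genotype test and camera were tested on simulated data with the depth of the proximal tubule-like sums and gene-wise dispersions. For the genotype test, changed genes were drawn from those above the median level, so lower genes were not covered. Of genes changed 2-fold, 4-fold, 8-fold and 16-fold, 14.8%, 91.6%, 98% and 98.8% were called, and 14% of all calls were unchanged genes (18% by DESeq2). With trended and common dispersions, 3.64% and 4.1% of calls were unchanged genes. The interaction test was simulated on proximal tubule-like and endothelial-like sums, with the same dispersion for all genes and changed genes above a minimum mean count. It called 1, 28, 43 and 49 of 50 genes at these folds and 3 unchanged genes. Camera called a list shifted 2-fold with the preset correlation and missed it with an estimated one, and called 0 of the others either way. Genes were drawn independently and lists at random, so false calls of lists whose genes vary together were not covered. Fisher's test called 1 shifted annotation class and 0 of 6 others. Here the others counted as called only if their odds ratio also lay beyond a set distance from 1. That limit was not used for the real regions, so false calls by adjusted p alone were not counted. R 4.3.3, Python 3.11.15, scipy 1.17.1 and numpy 2.4.6 were used. Fold changes against 0 counts are lower bounds from a floor of 3 counts over the group, and intervals of 95% and floors cover counting error only.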

Results

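Single-cell libraries of kidney were available from 2 wild type and 2 Gulo-/- samples, which differ in whether the gene for the last enzyme of vitamin C synthesis is intact. Totals were 10208946 and 61688164 UMIs in wild type replicates 1 and 2, and 10073836 and 88925323 in Gulo-/- replicates 1 and 2. After filtering, 1575, 7006, 1849 and 12403 cells remained, with median depths of 3729, 4876.5, 3014 and 4650 UMIs. Each genotype had a shallow and a deep library, and a female and a male one. Gulo itself had 0 and 2 UMIs in the wild type libraries and 0 and 2 in the Gulo-/- libraries, so its level was not measurable at this depth. Bisulfite sequencing of both genotypes was taken from the authors' deposited table of 86510 differentially methylated regions.

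The first comparison asked whether the make-up of the kidney's cell types differed with genotype. Proximal tubule-like cells, which reabsorb most filtered solutes, made up 83.2% ± 1.31 (SD, n = 2) of wild type cells and 36.7% ± 17.7 (SD, n = 2) of Gulo-/- cells. The share was 58.1 percentage points lower in the female Gulo-/- library and 34.9 points lower in the male one than in the wild type library of the same sex. Thick ascending limb-like cells made up 2.93% ± 0.0814 (SD, n = 2) and 15.96% ± 14.5 (SD, n = 2), and distal convoluted and connecting tubule-like cells 2.63% ± 0.505 and 14.04% ± 6.85 (SD, n = 2). The thick ascending limb-like difference was 23.25 percentage points in the female libraries and 2.81 in the male ones. With a mitochondrial limit of 25% the shares of this class overlapped between genotypes. Collecting duct principal cell-like cells made up 0.378% ± 0.354 and 4.66% ± 0.00636 (SD, n = 2). Intercalated cell-like cells made up 0.942% ± 0.344 and 4.37% ± 2.97, and thin limb-like cells 0.333% ± 0.248 and 1.82% ± 0.206 (SD, n = 2).

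Endothelial-like cells made up 3.52% ± 2.11 of wild type and 10.9% ± 8.09 (SD, n = 2) of Gulo-/- cells, but this difference was 14.6 percentage points in the male libraries and 0.144 points in the female ones. Stromal-like and urothelium-like cells were below 1% in every library, with means of 0.0778% and 0.0143% in wild type and 0.527% and 0.372% in Gulo-/-. Macrophage and monocyte-like cells (means 2.57% and 2.23%), T and NK cell-like cells (1.09% and 0.976%), B and plasma cell-like cells (0.577% and 0.699%), neutrophil-like cells (0.267% and 0.433%), erythroid cells (0.627% and 0.144%) and podocyte-like cells (0.00714% and 0.0927%) overlapped between genotypes. Unnamed clusters held 0.836% and 6.11%. In the proximal tubule-like and other non-overlapping classes the exact permutation p was 0.333, the smallest that this test allows for 2 against 2 libraries, so no share could pass it, and no model-based test of shares was run. The female-minus-male gap within the Gulo-/- genotype was also a gap between a deep and a shallow library.

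**Figure D1:**
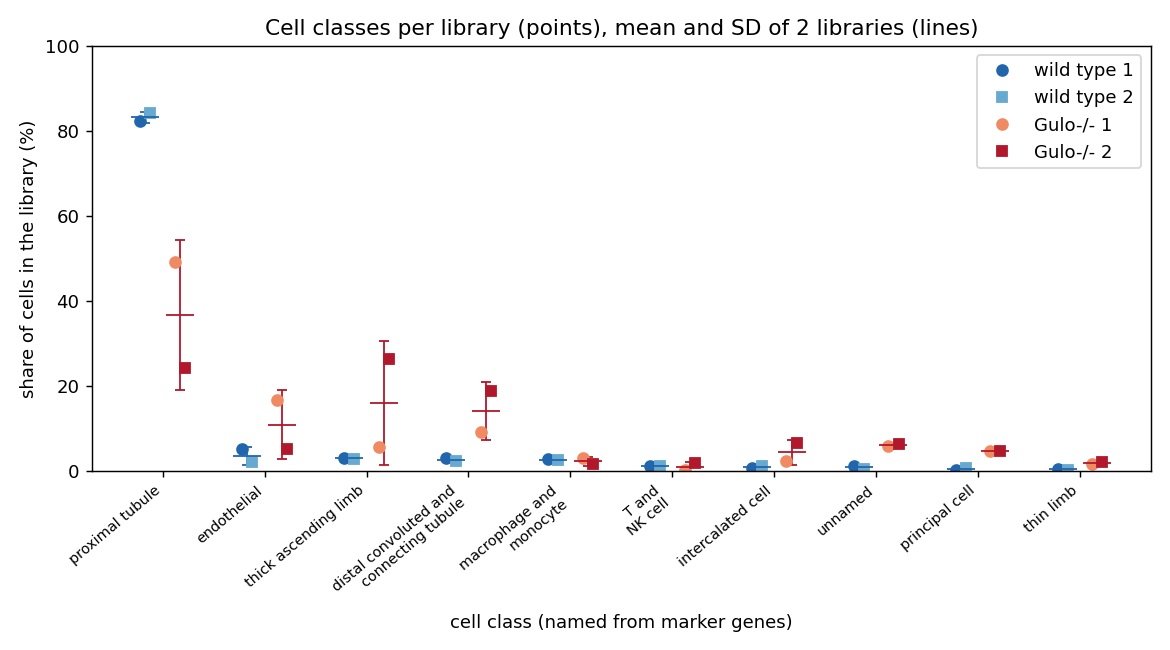
Percent of filtered cells (y axis) in the 10 commonest classes (x axis), with a point per library and lines for the mean and SD of 2 libraries. Proximal tubule-like cells lie at 82.3% and 84.1% in wild type and at 49.2% and 24.2% in Gulo-/- libraries.

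The second comparison asked which genes differed with genotype within proximal tubule-like cells. Of 11044 genes, edgeR called 27, with 13 higher and 14 lower in Gulo-/- cells. Of these, 6 of the higher and 2 of the lower genes were below their level in all cells. When only the 3459 genes at least as high in the class as in all cells were tested, 2 were called. Of the 27 genes, 19 were among those 3459, so most calls were lost in genes that pass this limit on level. These changes also compare different clusters of the class: clusters 1, 2, 10, 12, 14 and 18 held 99.54% of these cells in wild type replicate 2, 6.867% in wild type replicate 1 and 0.989% and 0.2001% in the Gulo-/- libraries, cluster 13 held 47.38% in wild type replicate 1, and clusters 4, 5, 7, 9 and 28 held 45.76% and 0.3902% in wild type and 97.69% and 99.6% in Gulo-/- libraries. S1-like clusters made up 328 of 1296 and 1157 of 5895 cells in wild type and 410 of 910 and 1499 of 2999 in Gulo-/- libraries, and S3-like clusters 24 and 1283 against 15 and 167. The S3-like cells of wild type replicate 2 lay in clusters 12 and 14 except for 2 cells, and those of the other libraries all lay in cluster 28. Serpina6, which encodes corticosteroid-binding globulin, had 0 UMIs in wild type and 148 in Gulo-/- cells and was at least 139.6-fold higher. Serpina1d and Serpina1b, which encode forms of alpha-1-antitrypsin, rose by log2 5.77 ± 0.34 and 4.22 ± 0.55 (SE, n = 2 per genotype, edgeR adjusted p = 0.00425 and 0.0499), and reads of this family can be shared between its close copies. Folh1, which encodes a folate hydrolase of the brush border, rose by 1.77 ± 0.24 (adjusted p = 0.0499).

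Among genes that fell, Mdk, which encodes the growth factor midkine, changed by log2 -5.86 ± 0.41 (SE, n = 2 per genotype, edgeR adjusted p = 0.00712), from 66.5 and 40.4 CPM to 1.03 and 0.851. Sectm1b changed by log2 -3.78 ± 0.28 (adjusted p = 0.0073), and Lgals1, which encodes galectin-1, by -3.32 ± 0.34 (adjusted p = 0.0341). Slc22a7, which encodes an organic anion transporter of the late proximal tubule, changed by -4.09, and Hpd, an enzyme of tyrosine breakdown, by -1.94. Apob, the structural protein of lipoproteins, changed by -2.48, Dnase1 by -1.88 and Acp5, an acid phosphatase, by -2.14. Keg1, at 2106 and 2121 CPM in wild type, changed by -2.69, and Isoc2b by -3.09 and Adtrp by -2.47. Rpgrip1 had 276 UMIs in wild type and 1 in Gulo-/- cells, a ratio of 97.51 with a counting interval of 17.36 to 3865.

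A group of called genes that rose is known from blood vessels. Rgcc (log2 3.16), Tm4sf1 (2.64), Klf2 (2.46) and Ly6c1 (2.26) belong to the authors' deposited marker list of endothelial cells, made from these libraries, and Sparcl1, a secreted matrix protein, had 1 UMI in wild type and 43 in Gulo-/- cells, a ratio of 121.7 (20.71 to 4918). Of 11 endothelial markers measured in proximal tubule-like cells, 0 were called over all genes and 10 rose when adjusted over the list alone. The list was higher with a camera adjusted p of 4.56e-08, and adjusted p = 0.443 with an estimated correlation. Markers of principal cells (adjusted p = 2.77e-04), thin limb (0.0236), intercalated cells (0.0236) and parietal epithelium (0.0210) were also higher and proximal tubule markers lower (0.0242), each at an adjusted p = 0.549 or above with an estimated correlation. The ribosomal genes Rpl36-ps3 (3.42) and Rpl6l (2.27), whose reads other copies can share, rose as well.

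The 23 named genes were chosen so that both Gulo-/- libraries lay on one side of both wild type libraries, and a further 4 called gene models have no name. With sex as a block, edgeR called 0 genes (1534 had an unadjusted p under 0.05, and adjusted p was 0.0585 for the lowest named gene). DESeq2's Wald test called 291, and edgeR with the replicate number as a block called 250. Without wild type replicate 1 the count was 261, without Gulo-/- replicate 1 it was 7 and without Gulo-/- replicate 2 it was 16. In the S1-like clusters alone, 75 of 10033 genes were called (3 with the sex block, and 360, 234 and 7 without wild type replicate 1, wild type replicate 2 and Gulo-/- replicate 2), and S3-like cells were too few to test. Of the 23 named genes, 15 were called there, Serpina1b, Folh1, Adtrp and Hpd were not, and Serpina6, Serpina1d, Sparcl1 and Slc22a7 were too low to be tested. The S1-like cells of wild type replicate 2 lay mainly in clusters 10 and 18 and those of the Gulo-/- libraries in clusters 4 and 9. Serpina1d, Folh1, Keg1, Mdk and Dnase1 are among the leading genes by which clusters 28, 9, 2, 18 and 18 differ from other clusters.

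**Figure D2:**
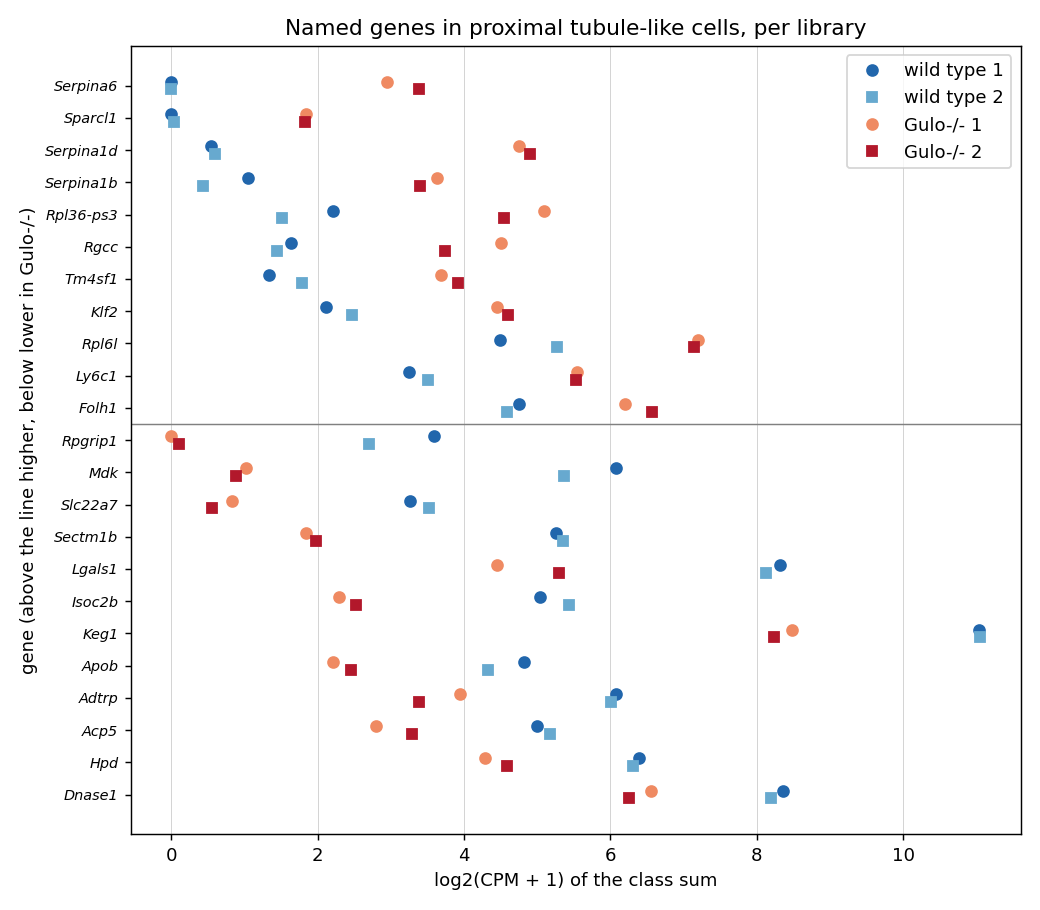
Level of each named gene in proximal tubule-like cells (x axis, log2 of CPM plus 1) by gene (y axis), with a point per library. The genes were chosen so that both Gulo-/- points lie on one side of both wild type points. Keg1 lies highest among the genes that fell, at 2106 and 2121 CPM in wild type.

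Of the 28 gene lists, 9 were called in proximal tubule-like cells with the preset correlation and 0 with an estimated one. Tubular injury genes had a median log2 change of 1.33 (camera adjusted p = 6.15e-04, adjusted p = 0.778 with an estimated correlation). None of its 29 measured members was called by edgeR over all genes, and when adjusted over the list alone 4 rose, Anxa2 (1.75), Cdkn1a (1.39), Myc (2.19) and Cxcl1 (2.52), and Plin2 fell (-1.18). Collagens and matrix genes had a median of 0.90 (adjusted p = 3.72e-05, adjusted p = 0.778 with an estimated correlation), with 14 of 14 members positive and 8 higher when adjusted over the list alone, among them Col4a2 (1.10), Vim (2.15), Acta2 (2.50) and Lamb2 (2.15). Vim, Acta2 and Lamb2 are also abundant in stromal and endothelial cells, and endothelial and stromal markers had medians of 1.82 and 1.5 in the same cells (camera adjusted p = 4.56e-08 and 0.196).

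Of the metabolic lists, 3 were called lower in proximal tubule-like cells. Fatty acid oxidation genes had a median of -0.47 (camera adjusted p = 6.15e-04), antioxidant enzymes of -0.39 (0.00228) and nuclear-encoded oxidative phosphorylation genes of -0.26 (0.00228), with adjusted p = 0.778, 0.778 and 0.881 with an estimated correlation. Proximal tubule markers had a median of -0.42 in the same cells (adjusted p = 0.0242). Gluconeogenesis and glycolysis (-0.26, adjusted p = 0.151), brush border and vitamin metabolism enzymes (-0.35, 0.343) and mitochondrially encoded genes (-0.12, 0.768) were not called. Cholesterol synthesis genes had a median of 0.63 (adjusted p = 0.00651), dissociation and immediate early genes of 0.64 (0.00228) and ribosomal protein genes of 0.25 (0.00126), with adjusted p = 0.778, 0.778 and 0.881 with an estimated correlation. In the immediate early list Klf2 was called, and 14 members rose and 5 fell when adjusted over the list alone. Without wild type replicate 1 the oxidative phosphorylation list turned upward (adjusted p = 0.884) and the fatty acid oxidation (0.209) and antioxidant (0.0969) lists were not called. The ribosomal list turned downward without wild type replicate 2 (adjusted p = 0.989), and the immediate early (0.167) and cholesterol (0.0807) lists were then not called. The ribosomal (0.62) and cholesterol (0.19) lists were not called without Gulo-/- replicate 1, nor the antioxidant list (0.0943) without Gulo-/- replicate 2.

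The lists of this paragraph were chosen for vitamin C or for the marks the other assays measured. In them edgeR called 0 genes over all genes in proximal tubule-like cells (1700 of all 11044 genes had an unadjusted p under 0.05). Enzymes outside these lists, such as the called Hpd, are not covered by this count. DNA methylation enzymes and readers had a median of 0.25 with 12 of 14 members positive (camera adjusted p = 0.0254, adjusted p = 0.778 with an estimated correlation, and 0.0993 without Gulo-/- replicate 2), including Tet1 (1.41), Tet2 (0.84), Tet3 (1.17) and Dnmt1 (1.16). The lists of ascorbate transport and synthesis (adjusted p = 0.623, 2 members higher when adjusted over the list alone), m6A writers, erasers and readers (0.886), Jumonji histone demethylases (0.139) and collagen modification (0.0926) were not called. Among their members, the ascorbate transporter Slc23a1 had a log2 change of 0.82 (edgeR adjusted p = 0.228), Mettl3 of -0.89 (0.245), Fto of -0.06 and Alkbh5 of 0.31.

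**Figure D3:**
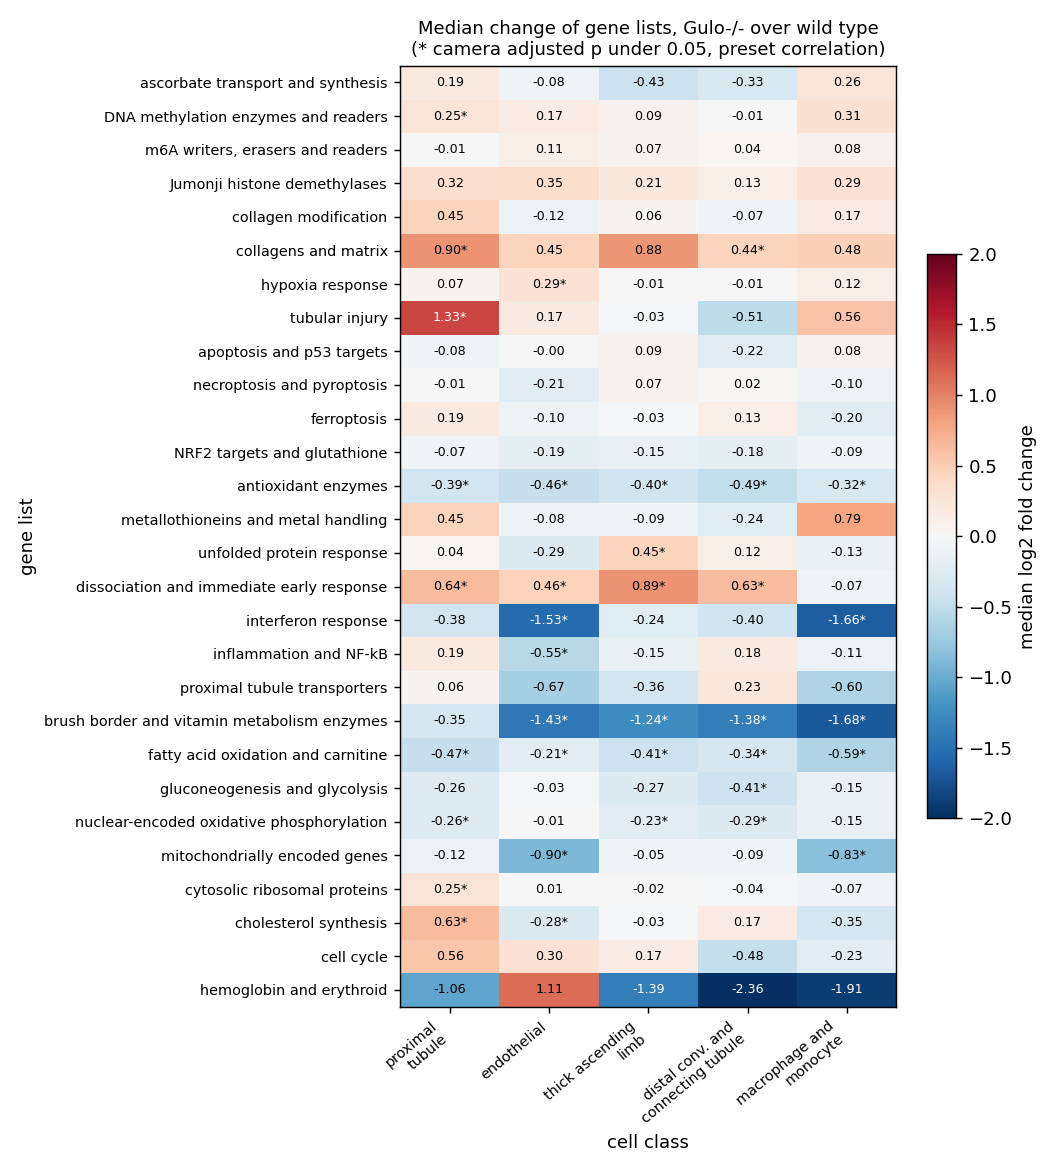
Median log2 change, Gulo-/- over wild type (colour and printed value), of 28 gene lists (y axis) in 5 cell classes (x axis), with an asterisk for a camera adjusted p under 0.05 at the preset correlation. Interferon response genes have medians of -1.53 in endothelial-like and -1.66 in macrophage and monocyte-like cells, and antioxidant enzymes are negative in all 5 classes.

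The third comparison was that of genotypes within endothelial-like cells. Of 6721 genes edgeR called 20, with 2 higher and 18 lower. The clusters of this class were mixed differently: cluster 25 held 2 of 79 and 12 of 142 cells in wild type libraries. In Gulo-/- libraries it held 31 of 307 and 246 of 640 cells. Gene and list changes in this class therefore also compare different clusters. Zbp1, a sensor of nucleic acids that can start necroptosis, changed by log2 -4.77 ± 0.56 (SE, n = 2 per genotype, adjusted p = 0.0325), and Ifi204, an interferon-induced DNA sensor, by -3.62 ± 0.50 (adjusted p = 0.0383). H2-DMb1, H2-Aa and Cd74, which load or form MHC class II, changed by -3.75, -3.13 and -2.73. Csf1, a growth factor of macrophages, changed by -2.64, Ifi27l2a by -2.89 and Pla2r1, a phospholipase receptor, by -3.96. Lrg1, a secreted glycoprotein, rose by 2.98 ± 0.40 (adjusted p = 0.0379), from 15.6 and 8.75 CPM to 82.3 and 102.3, and Rpl6l rose by 2.38.

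The interferon list had a median of -1.53 in endothelial-like cells (camera adjusted p = 1.4e-23, adjusted p = 0.604 with an estimated correlation). None of its 32 measured members was positive, 1 fell over all genes and 28 fell when adjusted over the list alone, among them Igtp (-2.28), Ifit1 (-1.87), Irf7 (-1.61) and Isg15 (-1.41). The inflammation list was lower (-0.55, adjusted p = 2.27e-04, and 0.604 with an estimated correlation), with Cd74, Csf1 and H2-Aa called, and the hypoxia list higher (0.29, adjusted p = 0.00872, and 0.604 with an estimated correlation), with Eno1 (1.06), Ankrd37 (2.40), Adm (2.03) and Slc2a1 (1.53) higher when adjusted over the list alone. Antioxidant enzymes (-0.46, adjusted p = 0.00158), cholesterol synthesis (-0.28, 0.0235), mitochondrially encoded genes (-0.90, 0.0329), fatty acid oxidation (-0.21, 0.0468) and immediate early genes (0.46, 0.0468) were also called. The immediate early list turned downward without wild type replicate 2 (adjusted p = 0.188), and the hypoxia (0.0885), antioxidant (0.167), cholesterol (0.0707), mitochondrially encoded (0.561) and fatty acid oxidation (0.322) lists were then not called. The immediate early (0.273) and fatty acid oxidation (0.392) lists were not called without Gulo-/- replicate 1, nor the mitochondrially encoded (0.329) and cholesterol (0.14) lists without Gulo-/- replicate 2. With an estimated correlation the adjusted p of the 9 lists called here was 0.529 or above. Dendritic cell markers were lower in these cells (adjusted p = 2.78e-04), endothelial markers were lower (0.0140), and principal cell, stromal, erythroid and thick ascending limb markers were higher, none with an estimated correlation (adjusted p = 0.291 or above over all marker lists).

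Gatm (-2.44), Cyp4b1 (-2.32), Fbp1 (-2.07) and Miox (-1.94), which are abundant in proximal tubule, fell in endothelial-like cells too. Their list of brush border enzymes had a median of -1.43 (camera adjusted p = 7.63e-11, adjusted p = 0.529 with an estimated correlation), and proximal tubule markers were lower (adjusted p = 1.05e-07, and 0.291 with an estimated correlation). EdgeR called 0 genes with the sex block (470 at an unadjusted p under 0.05), with a mitochondrial limit of 25% (559) and without doublet removal (662), and DESeq2's Wald test called 83. With the replicate number as a block, edgeR called 319. The counts without wild type replicate 1, Gulo-/- replicate 1 and Gulo-/- replicate 2 were 36, 231 and 80.

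In thick ascending limb-like cells, which take up salt from the urine, edgeR called 83 of 5913 genes, with 39 higher and 44 lower. Socs3, which dampens cytokine signals, rose by log2 3.47 ± 0.61 (SE, n = 2 per genotype, edgeR adjusted p = 6.85e-05). It was at 17.4 and 2.14 CPM in wild type (3 and 2 UMIs) and 29.6 and 63.7 in Gulo-/- libraries. Klf2, with 0 and 5 wild type UMIs, rose by 2.92. Lcn2, a marker of tubular injury, rose by 2.18 ± 0.50 (edgeR adjusted p = 0.00352) and Spp1, which encodes osteopontin, by 1.11. Lcn2 is also among the leading genes of the principal cell-like cluster. Principal cell markers had a median change of 1.24 in thick ascending limb-like cells, on the scale of log2 of CPM plus 1. Rpl36-ps3 and Sgk1, a kinase that regulates sodium transport, had 2 and 3 wild type UMIs and ratios of 12.49 (3.434 to 103.5) and 9.426 (3.203 to 45.89). Of 30 measured immediate early genes 9 were called, all higher, among them Dusp1 (2.54), Zfp36 (2.52), Egr1 (1.87) and Junb (1.87), and 12 when adjusted over the list alone (median 0.89, 21 positive, camera adjusted p = 0.00747, adjusted p = 0.811 with an estimated correlation). The list was not called without wild type replicate 2 (0.0702) or without Gulo-/- replicate 2 (0.26). Pecr (-3.11), Lgals1 (-3.10), Fmo1 (-2.91), As3mt (-2.82), Gatm (-2.19), Fbp1 (-1.98), Miox (-1.52) and Acaa1b fell. Pecr was at 17.4 and 127.5 CPM in wild type and at 16.4 and 9.71 in Gulo-/- libraries, so its fall rested mainly on wild type replicate 2. Proximal tubule markers were lower in these cells too, with a median of -1.70 (camera adjusted p = 8.06e-05, adjusted p = 0.591 with an estimated correlation), and 31 of the 44 lower and 25 of the 39 higher genes were below their level in all cells.

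In distal convoluted and connecting tubule-like cells, of 6645 genes edgeR called 72, with 29 higher and 43 lower. Grem1, an inhibitor of bone morphogenetic proteins, had 0 wild type and 492 Gulo-/- UMIs and was at least 13.86-fold higher. Car15, a carbonic anhydrase, Asb11 and Socs3 had ratios of 25.18 (6.941 to 208.4), 26.54 (4.728 to 1051) and 25.02 (4.455 to 991.4), from 2, 1 and 1 wild type UMIs. Lgals1 (-3.40), Fmo1 (-3.26), Eci3 (-3.26) and Zmynd10 (-3.19) fell, as did Gatm (-2.44), Ehhadh (-2.29), Acaa1b (-2.01), Msra (-1.71), Fbp1 and Miox (-1.65 each). Eci3 and Zmynd10 had 3 UMIs each in wild type replicate 1. Proximal tubule markers had a median of -1.65 (camera adjusted p = 1.84e-04, adjusted p = 0.714 with an estimated correlation), and 31 of the 43 lower and 15 of the 29 higher genes were below their level in all cells. Oxidative phosphorylation genes had a median of -0.29 (camera adjusted p = 1.04e-05, adjusted p = 0.739 with an estimated correlation).

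These counts in the distal classes rested on few cells, 47 in wild type replicate 1 for each class. The mix of clusters also differed between libraries. Cluster 6 held 8 of 47 and 10 of 201 thick ascending limb-like cells in wild type and 5 of 105 and 1059 of 3254 in Gulo-/-. Cluster 3 held 10 of 47 and 81 of 159 distal convoluted and connecting tubule-like cells in wild type and 81 of 170 and 1418 of 2342 in Gulo-/-. DESeq2's Wald test called 14 and 12 genes, and equal cell numbers per library left 1 and 2. The sex block gave 51 and 105 genes. The thick ascending limb-like count was 179 without wild type replicate 1, 26 without wild type replicate 2 and 46 without Gulo-/- replicate 2, and the distal count was 182 without wild type replicate 1 and 0 with a mitochondrial limit of 25% (edgeR, 220 at an unadjusted p under 0.05).

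The fourth comparison asked whether the genotype effect differed between cell classes. The interaction test of edgeR called 187 genes between endothelial-like and proximal tubule-like cells, of which 46 had a higher and 141 a lower effect in endothelial-like cells. Lrg1 differed by log2 3.61 ± 0.58 (SE, adjusted p = 1.43e-04), H2-DMb1 by -3.17 ± 0.57 (adjusted p = 5.41e-04) and Pla2r1, too low in proximal tubule-like cells to be tested there alone, by -7.92 ± 1.90 (adjusted p = 0.0121), while Zbp1 (-2.27, adjusted p = 0.88) and Ifi204 (-1.86, adjusted p = 0.913) were not called. Against proximal tubule-like cells, 233 genes were called for thick ascending limb-like, 233 for distal convoluted and connecting tubule-like and 24 for macrophage and monocyte-like cells. DESeq2's Wald test called 72, 0, 5 and 7 genes in these 4 comparisons (296 at an unadjusted p under 0.05 for the thick ascending limb). Without Gulo-/- replicate 2 the edgeR counts were 20, 6, 7 and 0 (251 at an unadjusted p under 0.05 for macrophage and monocyte-like cells), without wild type replicate 1 the endothelial, distal and macrophage counts were 361, 389 and 68, without wild type replicate 2 the thick ascending limb and distal counts were 54 and 135, and without Gulo-/- replicate 1 the macrophage count was 6.

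The fifth comparison was of DNA methylation between genotypes. The methylation levels are not split by cell type. In the single-cell libraries, proximal tubule-like cells made up 83.2% of wild type and 36.7% of Gulo-/- cells. A methylation change within cells can therefore not be told apart here from a different mix of cells. In the authors' deposited table of 86510 regions (mm10), 46552 had lower and 39958 higher methylation on side 1, whose genotype the table does not state. The share lower on side 1 in the authors' deposited table was 53.8% (exact Clopper-Pearson interval 53.5% to 54.1%), the median absolute difference was 0.192 and the median region held 6 CpGs. Promoter regions leaned furthest: in the authors' deposited table, 78.5% of 7867 were lower on side 1, an odds ratio of 3.47 against all other regions, with a p too small for the software to tell from 0. Regions in 5' UTRs (68.9%, odds ratio 1.91, adjusted p = 3.13e-14), 3' UTRs (64.2%, 1.55, 7.09e-20), exons (61.0%, 1.37, 6e-31), introns (59.4%, 1.44, 1.76e-147) and downstream of genes (59.0%, 1.24, 9.63e-04) followed in the authors' deposited table by Fisher's exact test. Among regions with at least 10 CpGs in the authors' deposited table, the odds ratios were 1.37 in 5' UTRs (adjusted p = 0.0507), 0.998 in 3' UTRs (1), 0.961 in exons (0.511) and 1.26 downstream (0.292), none past the threshold. Distal intergenic regions went the other way in the authors' deposited table, with 41.3% of 36370 lower on side 1 and an odds ratio of 0.415, but with at least 10 CpGs 59.55% of 5592 were lower on side 1 (odds ratio 0.441), against 72.0% of all such regions.

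**Figure D4:**
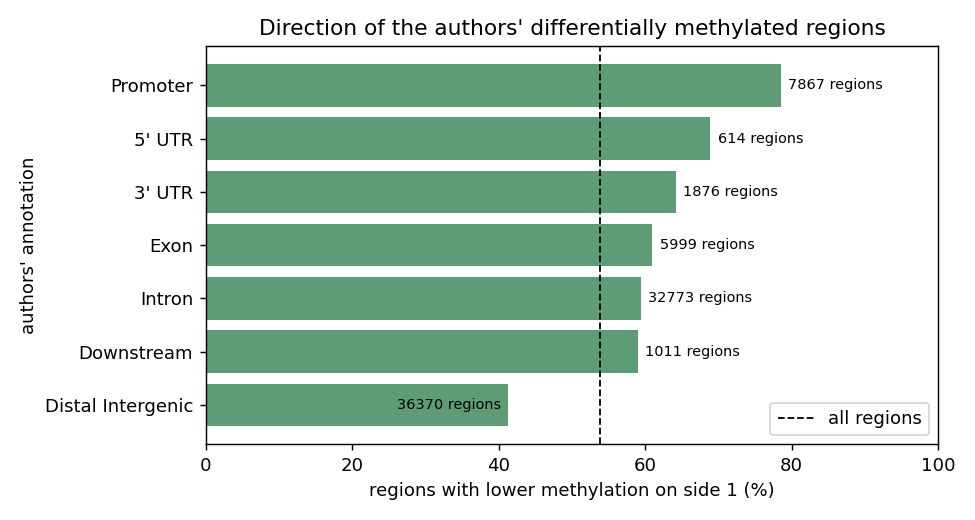
Percent of regions in the authors' deposited table with lower methylation on side 1 (x axis) by annotation class (y axis), with a dashed line for all regions. Promoter regions reach 78.5% and distal intergenic regions 41.3%, on either side of the 53.8% of all regions.

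Single promoters in the authors' deposited table differed by more than 0.3 in both directions. The promoter region of Slc4a4, a bicarbonate transporter of the proximal tubule (chromosome 5, 89028121 to 89028537, 14 CpGs), had levels of 0.296 on side 1 and 0.781 on side 2 in the authors' deposited table, and that of Ass1, an enzyme of arginine synthesis (chromosome 2, 31468828 to 31469459, 10 CpGs), 0.417 and 0.809. The other promoter regions lowest on side 1 in the authors' deposited table were those of BC037032 (-0.539), Srpk3 (-0.397), Mir185 (-0.397), Guca2b (-0.383), Shank3 (-0.372) and Prpf38b (-0.368). The highest on side 1 in the authors' deposited table were those of Col5a2 (0.435), a fibrillar collagen gene, Mir133a-2 (0.412), Hsd11b1 (0.409), which converts glucocorticoids, Samd4 (0.401), Gapdhs (0.397), Olfr747 (0.391), Slc7a8 (0.377) and Akap1 (0.363). The promoter region of Gulo (chromosome 14, 66009219 to 66009442) was at 0.208 and 0.402 in the authors' deposited table.

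Promoter regions of genes for ascorbate transport and synthesis were lower on side 1 in 8 of 8 cases in the authors' deposited table, those of m6A genes in 9 of 9 and those of DNA methylation enzymes and readers in 9 of 12, against 78.5% of all promoter regions, and these counts were not tested against that share. In a comparison chosen after the data were seen, all regions near proximal tubule markers were lower on side 1 in 77.1% of cases in the authors' deposited table and those near markers of the distal tubule, collecting duct and endothelium in 53.7% (Fisher's exact p = 9.98e-06), while their promoter regions were at 81.8% and 80% (p = 1). Genes with a promoter region in the authors' deposited table were not called as a set in proximal tubule-like cells. The 766 measured genes with a region higher on side 1 had a median log2 change of 0.10 and the 3133 with a region lower on side 1 of 0.09 (camera adjusted p = 0.288 for both, 0.402 with an estimated correlation), 1 and 9 of which were called by edgeR.

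The largest differences in the authors' deposited table gathered on chromosome 14, which carries Gulo (65986786 to 66009254), a pattern that was looked for only after the data were seen. Of 86 regions with an absolute difference of at least 0.5 in the authors' deposited table, 66 (76.7%) lay on this chromosome, which held 5.09% of all regions, and 64 of the 66 were higher on side 1. In the authors' deposited table, 65 of them lay between 45 and 80 Mb, and of the 20 regions of this size on other chromosomes 6 were higher on side 1. On the X chromosome 70.3% of regions in the authors' deposited table were higher on side 1.

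**Figure D5:**
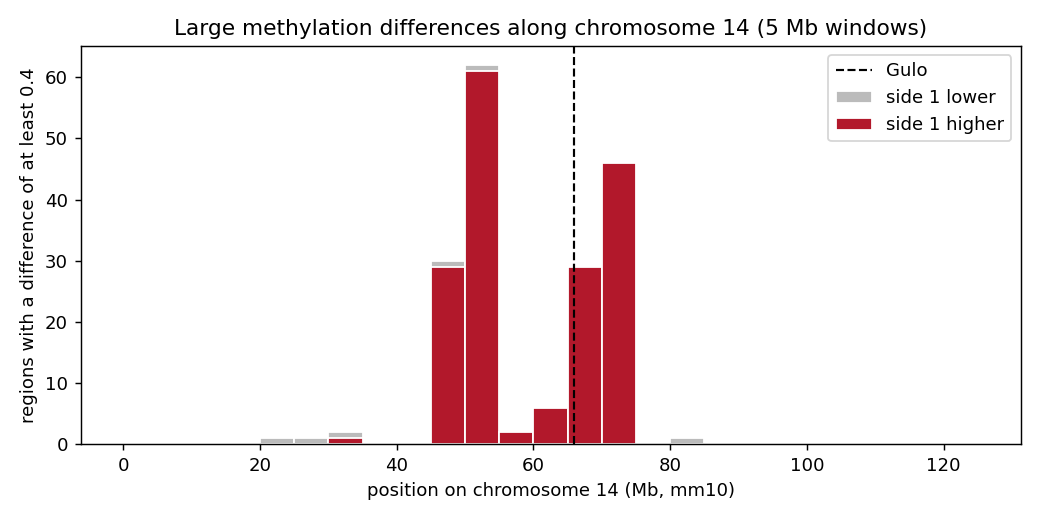
Number of regions in the authors' deposited table with an absolute difference of at least 0.4 (y axis, stacked by direction) in 5 Mb windows of chromosome 14 (x axis, Mb), with a dashed line at Gulo. Nearly all lie between 45 and 80 Mb and are higher on side 1.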

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

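Of the tests in this part, that of endothelial cells or doublets among proximal tubule-like cells, the interaction with endothelial-like cells with its alternatives, and the test of the immediate early list in proximal tubule-like cells were set before their results were seen; the other tests here, the use of that list to weigh dissociation, the comparisons by sex and the search for shared barcodes included, were chosen afterwards.

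Genes of other cell classes differed between genotypes within a class. On the scale of log2 of CPM plus 1, which gives smaller changes for low genes than the medians from edgeR, and over markers below their level in all cells, endothelial markers had median changes of 1.34 in proximal tubule-like cells and of 1.54, 1.85 and 1.30 in thick ascending limb-like, distal convoluted and connecting tubule-like and macrophage and monocyte-like cells, and proximal tubule markers of -1.28, -1.20, -1.06 and -1.48 in endothelial-like cells and those classes, against -1.59 in all cells. Endothelial cells or doublets counted as proximal tubule-like would bring many endothelial UMIs per cell (medians of 28 and 37 in endothelial-like cells of the Gulo-/- libraries), and this is argued against by the spread of these UMIs, of which at most 15.4% in Gulo-/- proximal tubule-like cells lay in cells with at least 3. Instead 26.6% and 25.8% of the Gulo-/- proximal tubule-like cells had at least 1 such UMI, against 9.72% and 16.2% in wild type. Free RNA of other cells, in a mix that follows the class shares, is a candidate explanation for the proximal tubule and endothelial markers. Their medians over the receiving classes lay within 0.421 and 0.554 of each other, as a source common to all classes would give. The endothelial-like share, however, differed by 0.144 percentage points in the female pair of libraries and by 14.6 in the male pair. Proximal tubule-like cells with at least 1 endothelial UMI rose from 9.72% in wild type to 25.8% in Gulo-/- in the female pair. In the male pair they rose from 16.2% to 26.6%. The female pair compares 1 library per genotype, and its shares leave out cluster 23, with 12 cells in wild type and 283 in Gulo-/-. Within wild type the percentage did not follow the share: replicate 2 had the lower endothelial-like share, 2.03% against 5.02%, but the higher percentage. This percentage therefore cannot decide whether a mix that follows the shares gave the female rise. Markers of other classes leave free RNA open. Medians of distal convoluted and connecting tubule, principal cell and intercalated cell markers lay within 0.454, 0.623 and 0.915 of each other but up to 1.34, 1.46 and 1.71 from the change in all cells. Those of thick ascending limb markers ran from -0.229 in distal convoluted and connecting tubule-like to 2.07 in macrophage and monocyte-like cells, a range of 2.301, and those of macrophage and monocyte markers from -0.557 in endothelial-like to 0.655 in distal convoluted and connecting tubule-like cells, a range of 1.21, which goes against a common source, while the markers measured in both classes differed by medians of 0.608 (SD 2.01, 4 markers) and 0.816 (SD 1.63, 8 markers), within their spread. A change of these genes inside proximal tubule cells with genotype stays open as well, also for the called genes Rgcc, Tm4sf1, Klf2 and Ly6c1.

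The share of proximal tubule-like cells was lower in both Gulo-/- libraries than in both wild type ones. A loss of these cells with every other class unchanged in number would raise every other share 3.77-fold on average, and is argued against by macrophage and monocyte-like cells, whose highest ratio between a Gulo-/- and a wild type library was 1.21, while the lowest ratio of distal convoluted and connecting tubule-like cells was 3.08. Removal of proximal tubule cells by the mitochondrial filter is argued against by proximal tubule marker UMIs over all barcodes, filtered or not, with shared ones left out. These UMIs were lower by log2 -2.28. They include those of Kap, which was highest in wild type replicate 2, but the S1 marker list, without Kap, was lower by log2 -1.70. Such sums mix the number of cells with the level per cell. Survival and capture of cells during dissociation may differ between libraries and cannot be told apart from a change in the kidney, because each library was a single dissociation, and immediate early genes, which dissociation also induces, were higher in proximal tubule-like cells (camera adjusted p = 0.00228, adjusted p = 0.778 with an estimated correlation, and 0.167 without wild type replicate 2). A biological change of several classes with genotype stays open and was not tested apart from this.

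The genotype effect differed between classes by the interaction test for 187 genes in endothelial-like, 233 in thick ascending limb-like, 233 in distal convoluted and connecting tubule-like and 24 in macrophage and monocyte-like cells, each against proximal tubule-like cells. Without Gulo-/- replicate 2 these counts were 20, 6, 7 and 0 (251 at an unadjusted p under 0.05 by edgeR, 7 called by DESeq2's Wald test on all libraries). Without wild type replicate 1 the endothelial, distal and macrophage counts were 361, 389 and 68, without wild type replicate 2 the ascending limb and distal counts were 54 and 135, and without Gulo-/- replicate 1 the macrophage count was 6. Among named genes, the log2 effect in endothelial-like minus proximal tubule-like cells was 3.61 for Lrg1, -7.92 for Pla2r1 and -3.17 for H2-DMb1. As3mt differed by -2.08 in thick ascending limb-like cells, and Fmo1 by -1.61 and Zmynd10 by -2.32 in distal convoluted and connecting tubule-like cells.

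Some share differences, Gulo-/- minus wild type in percentage points, went one way in the female pair of libraries and the other way in the male pair, a contrast between sexes that was not tested. They were 0.774 and -0.994 for T and NK cell-like, -1.19 and 0.505 for macrophage and monocyte-like, 1.04 and -0.791 for B and plasma cell-like, 0.694 and -0.363 for neutrophil-like and 0.185 and -0.0143 for podocyte-like cells, female value first.

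The barcodes of the 2 wild type libraries, which no comparison uses as a measurement, overlapped: 986 barcodes were common to both against 33.5 expected by chance. For these barcodes the profiles in both libraries had a median correlation of 0.695 across genes, and wild type replicate 2 had Xist at 546.3 CPM in them and at 0.121 CPM in its other barcodes.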

How the results depend on the processing

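Chosen after the data were seen were the sex block, keeping shared barcodes, cluster 23 as endothelial-like, the regions without chromosome 14, and every value for thick ascending limb-like (TAL), distal convoluted and connecting tubule-like (DCT) and macrophage and monocyte-like (MAC) cells. Causes of the changes below were not tested, unless fewer cells, genes or libraries in the alternative show them.

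The main counts of called genes were 27 in proximal tubule-like (PT), 20 in endothelial-like (EC), 83 in TAL, 72 in DCT and 0 in MAC cells (edgeR, 415 at an unadjusted p under 0.05 in MAC). DESeq2 size factors kept each of these counts within 1.5 times. DESeq2's Wald test called 291 in PT, 83 in EC, 14 in TAL, 12 in DCT and 14 in MAC cells. Without a filter on low counts edgeR called 857, 372, 170, 178 and 148. With only genes at least as high in the class as in all cells it called 2 in PT, 32 in EC and 31 in TAL cells. A mitochondrial limit of 25% gave 52 in PT, 0 in EC (559 at an unadjusted p under 0.05), 12 in TAL and 0 in DCT cells (220). Without doublet removal edgeR called 0 in EC (662 unadjusted) and 32 in DCT cells. Clustering each library alone gave 70 in PT, 41 in EC and 29 in TAL cells, and equal cell numbers gave 78 in PT, 1 in TAL and 2 in DCT cells. Keeping shared barcodes gave 67 in PT cells, and S1-like cells alone gave 75. The replicate block gave 250 in PT, 319 in EC, 141 in DCT and 171 in MAC cells. The labels do not say what the replicate number marks, and deviations of libraries with the same number correlated across genes at r = -0.0038 in PT, 0.221 in EC, -0.0415 in TAL, -0.0274 in DCT and 0.197 in MAC cells (genes are not independent replicates). The sex block gave 0 in PT (1534 unadjusted), 0 in EC (470) and 51 in TAL cells.

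Leaving out each library in turn gave 7 to 261 genes in PT cells (lowest without Gulo-/- replicate 1, 16 without Gulo-/- replicate 2, highest without wild type replicate 1) and 20 to 231 in EC cells (36 without wild type replicate 1, 80 without Gulo-/- replicate 2, highest without Gulo-/- replicate 1). In TAL cells it gave 26 to 179 (lowest without wild type replicate 2, 46 without Gulo-/- replicate 2, highest without wild type replicate 1), and in DCT cells 76 to 182 (highest without wild type replicate 1). In MAC cells it gave 0 to 227 (0 without Gulo-/- replicate 2, 73 without wild type replicate 2, 202 without wild type replicate 1, highest without Gulo-/- replicate 1). Of the 23 named PT genes none changed sign under any alternative run, but 23 were no longer called with the sex block, 19 without Gulo-/- replicate 1, 15 without Gulo-/- replicate 2 and 9 without wild type replicate 2. The 6 named EC genes kept their sign, and 6 were no longer called at the 25% limit, without doublet removal and with the sex block, 4 without wild type replicate 2, and 3 without wild type replicate 1 and with equal cell numbers. The 8 named TAL and 8 named DCT genes kept their sign wherever they were tested, and with the sex block 4 and 2 were no longer called.

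Interaction counts were 187 for EC, 233 for TAL, 233 for DCT and 24 for MAC cells against PT cells. DESeq2's Wald test called 72, 0 (296 unadjusted), 5 and 7. Without doublet removal the EC count was 120, without a filter on low counts the TAL count was 134, and at the 25% limit the TAL and DCT counts were 57 and 95. Leaving out a library gave 20 to 361 for EC (lowest without Gulo-/- replicate 2, highest without wild type replicate 1) and 6 to 290 for TAL (lowest without Gulo-/- replicate 2, 54 without wild type replicate 2). It gave 7 to 389 for DCT (lowest without Gulo-/- replicate 2, 135 without wild type replicate 2, highest without wild type replicate 1) and 0 to 68 for MAC (0 without Gulo-/- replicate 2, 251 unadjusted, 6 without Gulo-/- replicate 1, highest without wild type replicate 1).

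Over the alternatives run, the share difference in percentage points was -47.6 to -46.5 for PT, 9.715 to 13.1 for TAL, 7.24 to 10.9 for EC and 3.43 to 5.16 for intercalated cell-like cells. The SD in Gulo-/- libraries of TAL (14.5) and EC (8.09) exceeds the difference itself, so movement within it says little. At the 25% limit TAL shares overlapped between genotypes, at 2.08% and 0.856% in wild type and 1.76% and 20.6% in Gulo-/- libraries, and urothelium-like shares overlapped with separate clustering. At the 25% limit the difference was 6.50 for DCT, 5.69 for principal cell-like, 6.58 for unnamed, 2.29 for thin limb-like and 0.542 for urothelium-like cells. With separate clustering it was 6.67 for principal cell-like, 2.65 for erythroid (the opposite direction to the -0.483 of joint clustering), 1.28 for stromal-like and 0.878 for urothelium-like cells. Unnamed cells differed by 5.72 without doublet removal and by 4.02 with cluster 23 counted as endothelial-like.

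The preset correlation called 9 gene lists in PT, 9 in EC, 6 in TAL, 7 in DCT and 5 in MAC cells. With an estimated correlation camera called 0, 0, 0, 0 and 0 (0, 1, 0, 0 and 0 at an unadjusted p under 0.05), and fry called 0, 1, 0, 0 and 0 (2, 8, 1, 3 and 2). Leaving out a library gave 5 to 13 in EC (lowest without wild type replicate 2), 2 to 10 in TAL, 4 to 11 in DCT and 3 to 11 in MAC cells (lowest without wild type replicate 2 and highest without wild type replicate 1 in these 3, and 9 in MAC without Gulo-/- replicate 1). The oxidative phosphorylation list in PT cells turned upward without wild type replicate 1 (adjusted p = 0.884, range over left-out libraries 2.53e-09 to 0.884). The ribosomal list in PT cells turned downward without wild type replicate 2 (0.989, range 6.97e-09 to 0.989, and 0.62 without Gulo-/- replicate 1). The immediate early list in EC cells turned downward without wild type replicate 2 (0.188, range 1.33e-09 to 0.273, highest without Gulo-/- replicate 1).

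In the authors' deposited table the share of regions lower on side 1 was 53.8%, and 59.4% at a difference of at least 0.2, 58.5% with at least 5 CpGs, 72.0% with at least 10 CpGs, 55.1% on autosomes and 54.4% without chromosome 14. With at least 10 CpGs the odds ratios were 0.998 in 3' UTRs, 1.37 in 5' UTRs, 1.26 downstream and 0.961 in exons, none past the threshold, while promoter, intron and distal intergenic regions kept an odds ratio past it on the same side of 1. The share of distal intergenic regions lower on side 1 itself turned, from 41.3% to 59.55%. The promoter sets were not called under any alternative run.

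S3-like cells were too few to test, separate clustering named 0 DCT cells in wild type replicate 1 (105, 100 and 1898 in wild type replicate 2 and Gulo-/- replicates 1 and 2), so DCT genes were not tested with it, and no thin limb-like cells were named by it in any library. Depth limits what can be seen of low genes: in wild type replicate 1 the TAL, DCT and MAC sums held 171857, 200307 and 188038 UMIs, against 7271338 in PT cells.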

Other observations

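In macrophage and monocyte-like cells, interferon response genes were lower in the Gulo-/- libraries as a list. Their median log2 change was -1.66 (camera adjusted p = 5.27e-17, adjusted p = 0.82 with an estimated correlation), 0 of 23 measured members were positive, and 18 fell when adjusted over the list alone. Ifi27l2a was at -2.73 (edgeR adjusted p = 0.144) and Irf7 at -2.43 (0.172). EdgeR called 0 of 4913 genes in these cells (415 at an unadjusted p under 0.05, and 14 called by DESeq2's Wald test), and without wild type replicate 1, wild type replicate 2 and Gulo-/- replicate 1 it called 202, 73 and 227. Brush border enzymes (-1.68, camera adjusted p = 1.6e-06), mitochondrially encoded genes (-0.83, 4.17e-04), fatty acid oxidation (-0.59, 0.00381) and antioxidant enzymes (-0.32, 0.0188) were lower too, each at an adjusted p of 0.82 with an estimated correlation. The mitochondrially encoded (adjusted p = 0.106), fatty acid oxidation (0.407) and antioxidant (0.621) lists were not called without wild type replicate 2, nor were the antioxidant list without Gulo-/- replicate 1 (0.0656) and the antioxidant (0.0636) and mitochondrially encoded (0.159) lists without Gulo-/- replicate 2. Markers of other cell types went both ways in the same cells. Dendritic cell markers had a median of -1.25 (camera adjusted p = 0.00449) and proximal tubule markers of -2.17 (6.57e-08), while thick ascending limb markers had one of 2.51 (0.0248) and the 2 measured principal cell markers one of 3.37, too few to test, with adjusted p = 0.4575, 0.4575 and 0.693 with an estimated correlation over the tested marker lists.

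In thick ascending limb-like cells the unfolded protein response list was higher (median 0.45, camera adjusted p = 0.00726), and brush border enzymes (-1.24, 1.19e-04), fatty acid oxidation (-0.41, 1.96e-04), antioxidant enzymes (-0.40, 0.00145) and oxidative phosphorylation genes (-0.23, 0.00183) were lower, at adjusted p = 0.811 or above with an estimated correlation. The unfolded protein (0.263), brush border (0.0702) and antioxidant (0.31) lists were not called without wild type replicate 2, nor was oxidative phosphorylation without wild type replicate 1 (0.733). In distal convoluted and connecting tubule-like cells antioxidant enzymes (-0.49, 7.9e-05), fatty acid oxidation (-0.34, 2.19e-04), brush border enzymes (-1.38, 0.00222) and gluconeogenesis genes (-0.41, 0.00911) were lower, and collagens and matrix (0.44, 0.0105) and immediate early genes (0.63, 0.041) were higher, at adjusted p = 0.707 with an estimated correlation, and in the same cells the 3 measured endothelial markers had a median of 1.73 (camera adjusted p = 2.81e-04, adjusted p = 0.454 with an estimated correlation). Without wild type replicate 2 the antioxidant (0.0946), fatty acid oxidation (0.0911), brush border (0.442), matrix (0.0859) and immediate early (0.307) lists were not called, nor were the matrix list without wild type replicate 1 (0.111) or Gulo-/- replicate 1 (0.0911) and the immediate early list without Gulo-/- replicate 2 (0.152). Clu, which encodes clusterin, fell by 1.21 on the log2 scale there. Jund (1.39), Fosb (1.68) and Btg2 (1.51) rose in thick ascending limb-like cells.

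The tests in this paragraph were chosen after the result was seen. The largest methylation differences in the authors' deposited table gathered on chromosome 14. Of the regions with a difference of at least 0.5 in the authors' deposited table, 75.6% lay within 45 to 80 Mb, around Gulo at 66 Mb, but the window was drawn around these regions, so this share decides nothing. DNA of another mouse strain, carried along with the disrupted gene through backcrossing, and a regional effect of the disrupted gene on methylation both stay open and cannot be told apart, as sequence reads were not analysed here.

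In the same window lay 3 of the 25 called genes with a known position in proximal tubule-like cells, Rgcc, Rpgrip1 and a gene model, so that 1.5% of the genes tested there were called and 0.215% elsewhere (Fisher's exact p = 0.0117, adjusted p = 0.0583 over 5 such comparisons, all made after the window was seen). The p was 0.0456 in S1-like, 0.308 in endothelial-like, 0.379 in thick ascending limb-like and 0.117 in distal convoluted and connecting tubule-like cells (adjusted p = 0.114, 0.379, 0.379 and 0.195), so the excess passed in none of them.

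The authors' deposited table of marker genes has 13 clusters. One of 79 genes, led by Napsa, Serpina1a and Aadat, had 58 genes at their highest in proximal tubule-like cells. These lead a cluster of 24 of 1575 and 2 of 7006 cells in the wild type libraries. In the Gulo-/- libraries it held 15 of 1849 and 167 of 12403 cells, so its share overlapped between genotypes.

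Over all cells Kap, a proximal tubule marker, was at 18050 CPM in the male and 1902 CPM in the female wild type library, and at 2041 CPM in the male and 162.1 CPM in the female Gulo-/- library. In the same order Cyp4b1 was at 915.3, 61.48, 67.15 and 16.74 CPM, and both genes were chosen after their values were seen. Lcn2 was at 0.236 and 13.2 CPM in wild type and at 123.5 and 58.5 CPM in Gulo-/- libraries, and Havcr1 was at 1 and 8 UMIs in wild type and 2 and 10 in Gulo-/- libraries. Lcn2 is among the leading genes of the principal cell-like cluster, a class at 0.378% of wild type and 4.66% of Gulo-/- cells.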
